A study of Oryza sativa with 48 samples.

How the data were processed

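RNA of the root and the 2nd leaf of rice seedlings was sequenced in 48 libraries, 3 for each of 16 groups (2 tissues, WT and aoc, and 0, 1, 6 and 72 h). Per the labels, plants grew in hydroponics for 11 days at 28 °C with 12 h of light and 60% humidity before 100 mM NaCl was given, each library is a biological replicate of 3 plants, RNA had a RIN of at least 6, and reads were paired ends of 150 bp. Root RNA was extracted with an RNeasy kit and leaf RNA with Tri-Reagent, so tissue and kit go together. The labels give the genotypes by name and not how aoc was made or in which background.

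The values used are raw read counts per gene, as deposited by the authors in 1 table of 35667 rice identifiers; the authors' notes in the labels name fastp, HISAT2, DESeq2 and the genome build IRGSP-1.0 without versions. The counting tool, the strand setting, the annotation release and any filter are not given in the sources used here. All 48 columns of the table were used, 3032 identifiers had no read in any library, and 0 rows named no gene. Of the identifiers, 1 was found in the reference table, which follows another assembly, so the files do not pair identifiers with names. For this reason the gene for allene oxide cyclase, the 27 gene lists fixed beforehand (0 members matched) and markers of other tissues were not analysed here. No library pair within a group was a copy of another, with a chi-square per degree of freedom of 16.5 to 66.3 in root and 26.4 to 289 in leaf.

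Total counts were 28.6 M to 71.7 M in root and 29.9 M to 41 M in leaf, so the floor of 3 counts in 1 library lay at 0.0419 to 0.105 CPM in root and 0.0731 to 0.100 CPM in leaf. Against a group without a read, the fold is given as a lower bound with 3 counts over the group's 3 libraries as the floor. With 1 to 3 reads the ratio stands with a 95% counting interval. The sequenced reads carry no molecular identifiers, so floors and intervals cover counting error only.

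Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr by group, robust quasi-likelihood fit, F test) and limma 3.58.1 as its base. The 24 libraries of a tissue entered 1 fit of group means, with 26195 identifiers tested in root and 24317 in leaf, and all 48 libraries entered the fit for differences between tissues, with 27323. Over 29 comparisons, 12 were changes from 0 h, 8 aoc minus WT at 1 hour, 6 the difference between the genotypes' changes and 3 the difference between the WT changes in root and leaf (root minus leaf). An identifier was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and every adjusted p of an identifier in the text comes from edgeR. The SE of a log2 fold change is its size over the root of its F statistic. Levels are CPM with TMM factors, as mean ± SD of 3 libraries. Overlaps were tested by Fisher's exact test, two-sided, within 1 family per table. It counts identifiers as independent, though they can vary together between libraries. Calls from 1 fit also share its estimate of the spread, which tends to raise their overlap above that of independent calls. Correlations of log2 fold changes are across genes and describe only. In hours that share the 0 h libraries, the covariance was set against 20 simulated sets without changed genes. Neighbouring identifiers were counted in the order of their numbers, with 2000 permutations.

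The comparisons, their tests, the alternatives and the rule for naming identifiers were set before the data were examined. The rule took the largest rises and falls of each comparison, up to 6 per direction, with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, a reference name, and, for 2 groups, all libraries of 1 above all of the other. No identifier had a usable reference name, so that condition was dropped and at most 2 per direction, from the top of each ranking, are printed. Sets of several identifiers, such as the run on chromosome 11, were described after their values were seen.

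The alternatives set beforehand were RLE size factors, no filter on low counts, DESeq2 1.42.0 with its own factors and independent filtering, the replicate number as a block, a fit of the compared groups alone, and leaving out each library in turn, where a group keeps 2 libraries and the spread is pooled over the groups. After the data were seen, 4 were added: root WT 1 h replicate 3 thinned to the median root total, the same alternatives for the derived counts, leaf aoc 0 h replicate 3 and leaf WT 1 h replicate 3 both left out, and the 6 leaf 72 h libraries left out of the fit. Other splits of the libraries were counted over all 10 splits for 2 groups, and over the real split with random draws for differences between changes: 30 draws per result within a tissue and 45 between tissues. The last number was raised from 30 after a first outcome had been seen, because at 72 h it varied with the draw: another split reached the real count in 1 set of draws and none did in a later set. The test was tried on simulated data with 200 changed genes, 50 at each of 1.5, 2, 4 and 8-fold, in libraries without other differences. For the change from 0 h it recovered 4%, 54%, 76% and 96% of them in root with 7 false calls, and 6%, 30%, 68% and 82% in leaf with 4. For differences between the genotypes' changes it made 5 false calls in each tissue, and between tissues it recovered 0%, 30%, 50% and 74% with 1 false call. With so few changed genes the adjusted cut-off is stricter than in comparisons with many calls, to which these shares do not carry over.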

Results

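Transcripts of rice seedlings were counted by RNA sequencing in the root and the 2nd leaf of the wild type Kitaake (WT) and of the genotype labelled aoc, before salt (0 h). The same was done after 1, 6 and 72 h in 100 mM NaCl. The series title concerns jasmonate signalling and salt tolerance in rice, and its stated design sets the responses of the 2 genotypes side by side. Jasmonates are plant stress hormones, and allene oxide cyclase, abbreviated AOC, is an enzyme of their synthesis. The 48 libraries formed 16 groups of 3. Total counts per library ranged from 28.6 M to 71.7 M in root (median 32 M) and from 29.9 M to 41 M in leaf (median 32.7 M). The deepest library was root WT 1 h replicate 3, and the next deepest root library held 39.2 M. Between replicates of a group, log2 CPM (counts per 1 M counts of the library, with TMM factors) correlated across genes at 0.961 to 0.989 in root and 0.908 to 0.983 in leaf. The median SD of log2 CPM between replicates was 0.400 in leaf WT 72 h and 0.420 in leaf aoc 72 h, against 0.201 to 0.255 in the other leaf groups and 0.164 to 0.216 in root. The files do not pair the gene identifiers with names, so identifiers are given without one, at most 2 per direction and comparison. For every identifier named under a comparison of 2 groups, all 3 libraries of 1 group lay above all 3 of the other.

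The first comparisons asked which transcripts of WT root differed from 0 h after each time in NaCl. At 1 h, 4589 of 26195 tested identifiers were higher and 4335 lower, and 1923 and 1133 of these differed at least 2-fold. Os05g0206000 rose from 1 read over the 3 libraries at 0 h to 30.4 ± 5.07 CPM (SD, n = 3). The ratio was 3163, with a 95% counting interval of 567 to 124974 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.62e-09). It was at 0.677 ± 0.365 CPM at 6 h and 0.0668 ± 0.0343 CPM at 72 h. Os03g0723400 rose from 0.130 ± 0.126 to 142 ± 66.8 CPM at 1 h, a log2 fold change of 10.08 ± 1.42 (SE; edgeR adjusted p = 2.26e-05). It was at 9.27 ± 0.949 CPM at 6 h. Os08g0113000 fell from 60.7 ± 6.60 to 1.38 ± 0.420 CPM at 1 h, a log2 fold change of -5.43 ± 0.42 (edgeR adjusted p = 2.01e-08). It was at 28.6 ± 6.30 CPM at 6 h and 59.7 ± 27.1 CPM at 72 h.

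At 6 h, 3406 identifiers were higher and 3117 lower in WT root than at 0 h (1688 and 809 at least 2-fold). Os10g0399200 had no read at 0 h and 28.6 ± 24.9 CPM at 6 h, at least 967-fold higher (edgeR adjusted p = 0.000236; floor of 3 counts over the group). Os06g0701700 fell from 118 ± 37.8 to 2.01 ± 0.634 CPM, a log2 fold change of -5.88 ± 0.97 (edgeR adjusted p = 0.000351). At 72 h, 2407 were higher and 2548 lower (874 and 832 at least 2-fold). Os01g0968100 rose from 1 read to 6.37 ± 2.71 CPM, a ratio of 627 with a counting interval of 112 to 24787 (edgeR adjusted p = 0.00329). Os05g0217800 fell from 43.7 ± 40.2 to 0.196 ± 0.214 CPM, a log2 fold change of -7.87 ± 1.87 (edgeR adjusted p = 0.00850). Without WT 0 h replicate 3 the total at 6 h dropped from 6523 to 4306. The total at 72 h, 4955, became 2215 without WT 0 h replicate 3, 2429 without WT 0 h replicate 2 and 2779 without WT 72 h replicate 2. It was 2522 with the compared groups alone in the fit.

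Many identifiers were called in the same direction at more than 1 hour in WT root. Of those higher at 1 h, 1512 were also higher at 6 h, against 597 if the calls were independent, and 1273 were lower at both hours, against 516. At 6 and 72 h, 1120 were higher at both (313 if independent) and 1206 lower at both (303). Between 1 and 72 h, 688 were higher at both (422 if independent) and 750 lower at both (422), and 424 were called in opposite directions. The hours share the 0 h libraries, which alone makes changes covary. They also share the spread estimate of 1 fit. In 20 simulated sets without changed genes the average overlap was 0 for each pair of hours. Without changed genes few calls can be made, so this 0 does not show how much the shared libraries add to the overlaps. The covariance of the log2 fold changes was 0.331 at 1 and 6 h, 0.222 at 6 and 72 h and 0.118 at 1 and 72 h, against 0.0282, 0.0297 and 0.03003 on average in the simulated sets. The correlation at 1 and 72 h, 0.259, lay below the simulated 0.509. No untreated plants were sampled at 1, 6 or 72 h, so each change from 0 h also holds hour of day and plant age.

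In aoc root, 4746 identifiers were higher and 4339 lower at 1 h, 4381 and 4353 at 6 h, and 2478 and 2711 at 72 h. Os05g0206000 again led the rises at 1 h, from 3 reads to 36.2 ± 11.1 CPM (SD, n = 3), a ratio of 1199 with a counting interval of 410 to 5817 (edgeR adjusted p = 6.25e-09). Os06g0127100 rose from 0.173 ± 0.0879 to 92.2 ± 26.7 CPM, a log2 fold change of 8.98 ± 0.60 (edgeR adjusted p = 3.04e-09). Os08g0113000 led the falls at 1 h, from 33.6 ± 3.34 to 0.934 ± 0.609 CPM (-5.17 ± 0.44 on the log2 scale; edgeR adjusted p = 6.49e-08). At 6 h Os05g0237800 rose from no read to 7.74 ± 8.82 CPM, at least 257-fold (edgeR adjusted p = 0.00183). Os06g0701700 fell from 178 ± 96.3 to 3.17 ± 0.444 CPM (-5.81 ± 0.95 on the log2 scale; edgeR adjusted p = 0.000226). At 72 h Os12g0630200 rose from 0.0427 ± 0.0740 to 9.61 ± 15.3 CPM (7.51 ± 1.67 on the log2 scale; edgeR adjusted p = 0.00521). That call was lost without aoc 72 h replicate 2, where the log2 fold change was 3.88 (adjusted p = 0.0909), and with the compared groups alone in the fit (0.0858). Os11g0179700 fell from 34.5 ± 21.0 to 1.94 ± 1.14 CPM (-4.15 ± 0.70 on the log2 scale; edgeR adjusted p = 0.000787). The total at 72 h, 5189, became 2373 without aoc 72 h replicate 2, 2605 without aoc 0 h replicate 2, 3097 without aoc 72 h replicate 3 and 2100 with the compared groups alone in the fit.

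The root responses of the 2 genotypes, which share no library, overlapped at every hour. Both were called from 1 fit with a common estimate of the spread. An identifier with a low spread or high counts thus tends to be called in both, and the number expected from independent calls is a low reference. At 1 h, 3624 identifiers were higher and 3124 lower in both genotypes, 4.36 and 4.35 times the number expected from independent calls. At 6 h, 2611 and 2539 were shared, 4.58 and 4.90 times the expected number, and at 72 h, 1294 and 1531, 5.68 and 5.81 times. Opposite calls, with WT higher and aoc lower, numbered 9 at 1 h, 2 at 6 h and 0 at 72 h, and with WT lower and aoc higher 0, 0 and 2. Across the 17531 identifiers with enough counts, which are not independent replicates, the log2 fold changes of WT and aoc correlated at Pearson r = 0.930 at 1 h, 0.916 at 6 h and 0.662 at 72 h (Spearman 0.870, 0.870 and 0.771). With the compared groups alone in the fits, the shared identifiers at 72 h numbered 1074 rather than 2825. They numbered 1571 and 1729 without WT 0 h replicates 3 and 2, 1766 without WT 72 h replicate 2, 1709 without aoc 0 h replicate 2 and 1554 without aoc 72 h replicate 2.

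**Figure D1:**
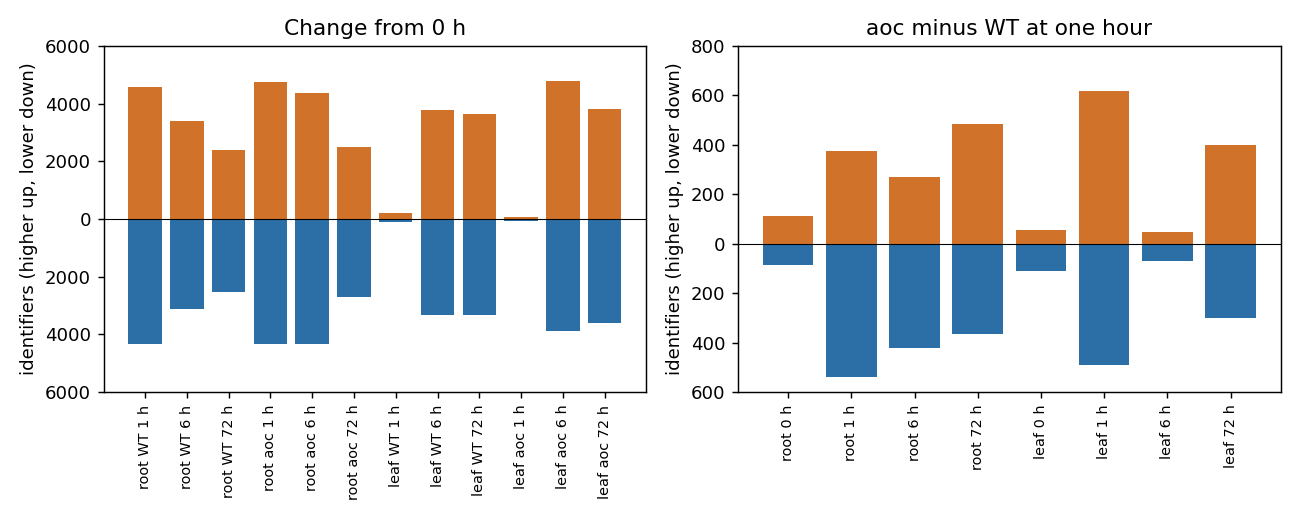
Number of identifiers called higher (orange, above 0) and lower (blue, below 0) by edgeR quasi-likelihood, on the left after 1, 6 and 72 h in NaCl against 0 h for each tissue and genotype, and on the right in aoc against WT at each hour; the 2 vertical axes differ in scale. With higher and lower added, root counts were highest at 1 h in both genotypes, whereas the leaf counts at 1 h were 199 and 112 in WT and 79 and 80 in aoc, far below those at 6 and 72 h.

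The leaf comparisons asked the same of the 2nd leaf. At 6 h, 3789 identifiers were higher and 3319 lower in WT leaf than at 0 h (2351 and 1648 at least 2-fold). In aoc leaf the numbers were 4778 and 3874 (2836 and 2069 at least 2-fold). Os07g0529600 rose from 2.29 ± 0.822 to 4224 ± 1082 CPM in WT leaf at 6 h (SD, n = 3), a log2 fold change of 10.85 ± 1.88 (edgeR adjusted p = 0.000443). In aoc leaf it went from 15.1 ± 22.2 to 5344 ± 415 CPM (8.47 ± 1.71 on the log2 scale; edgeR adjusted p = 0.000905). In WT root it went from 36.3 ± 7.42 to 1592 ± 384 CPM (5.46 ± 1.11; edgeR adjusted p = 0.00171). Os07g0178700 fell from 818 ± 389 to 4.52 ± 0.482 CPM in WT leaf (-7.50 ± 1.09 on the log2 scale; edgeR adjusted p = 0.000139). Os01g0871900 led the rises in aoc leaf, from 2 reads to 17.9 ± 7.90 CPM, a ratio of 845 with a counting interval of 233 to 6980 (edgeR adjusted p = 0.000797). Os08g0187900 fell in aoc leaf from 191 ± 94.2 to 0.335 ± 0.0971 CPM (-9.15 ± 1.15 on the log2 scale; edgeR adjusted p = 2.14e-05).

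**Figure D2:**
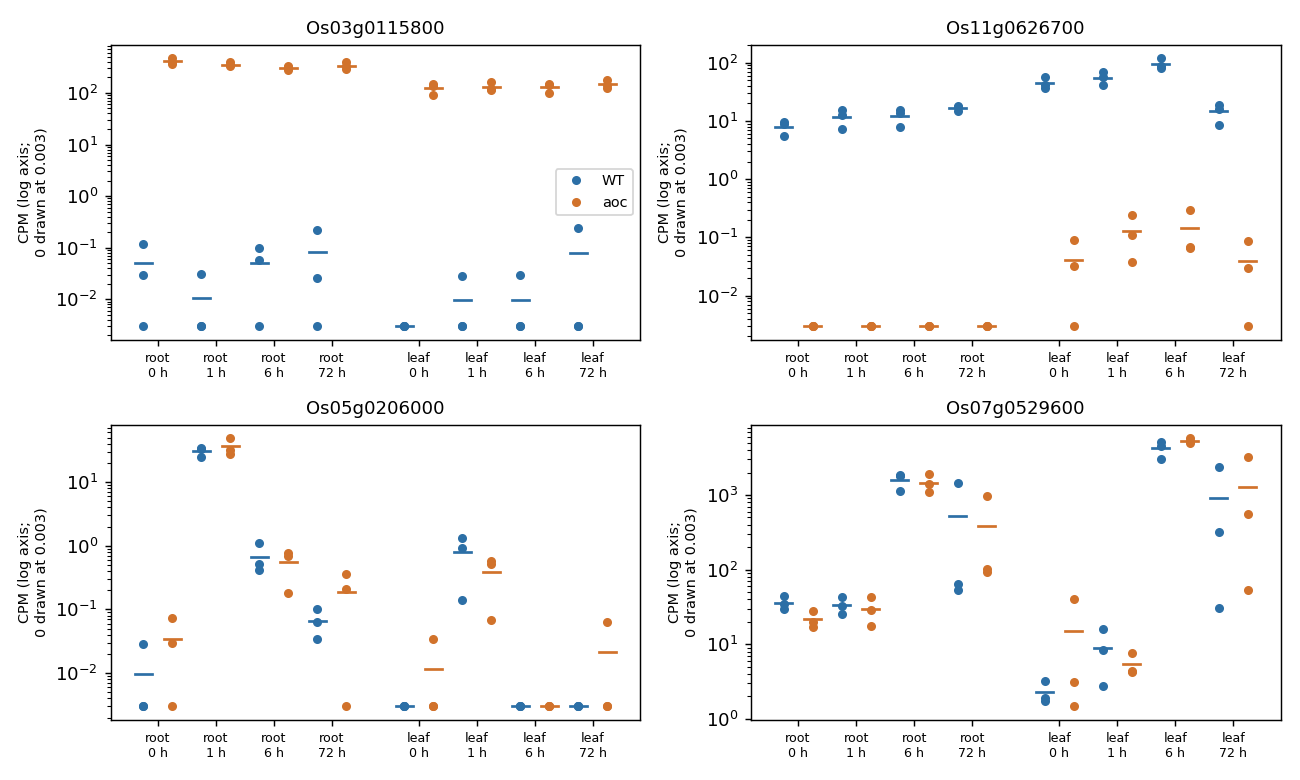
Level in CPM (log axis, 0 drawn at 0.003) of 4 identifiers in each root and leaf library by hours in NaCl, with WT in blue, aoc in orange and a bar at each group mean. Group means of Os03g0115800 were 125 to 412 CPM in aoc and at most 0.0831 CPM in WT, Os11g0626700 was at 0 in every aoc root library, Os05g0206000 peaked in root at 1 h and Os07g0529600 in both tissues at 6 h.

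At 72 h, 3648 identifiers were higher and 3316 lower in WT leaf (2242 and 1552 at least 2-fold), and 3823 and 3599 in aoc leaf (2274 and 1747 at least 2-fold). Os05g0217800, which also fell in WT root at 72 h, fell in WT leaf from 126 ± 41.0 to 2.24 ± 2.05 CPM (SD, n = 3), a log2 fold change of -5.80 ± 0.62 (edgeR adjusted p = 6.06e-05). In aoc leaf it fell from 291 ± 79.7 to 45.1 ± 22.5 CPM (-2.69 ± 0.53 on the log2 scale; edgeR adjusted p = 0.00138). Os03g0693700 led the rises in WT leaf, from no read to 41.5 ± 50.6 CPM, at least 1467-fold (edgeR adjusted p = 0.0346). That call was lost without WT 0 h replicate 1 (adjusted p = 0.0819), replicate 2 (0.0865) or replicate 3 (0.0890) and without WT 72 h replicate 2 (0.0569) or replicate 3 (0.0924), and also without the filter on low counts (0.0567). Os09g0452700 led the rises in aoc leaf, from 0.202 ± 0.116 to 112 ± 190 CPM (9.07 ± 2.43 on the log2 scale; edgeR adjusted p = 0.01005). It lost its call without aoc 72 h replicate 2, where the log2 fold change was 3.28 (adjusted p = 0.213), and with the compared groups alone in the fit (0.0824). The WT total of 6964 became 4132 without WT 0 h replicate 3, 3561 without WT 72 h replicate 3 and 1766 with the compared groups alone. The aoc total of 7422 became 4382 without aoc 0 h replicate 2 and 1508 with the compared groups alone.

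At 1 h the leaf counts were small, 199 higher and 112 lower in WT and 79 and 80 in aoc. Os02g0824500 rose in WT leaf from 0.141 ± 0.0744 to 21.9 ± 6.59 CPM (SD, n = 3), a log2 fold change of 7.24 ± 1.47 (edgeR adjusted p = 0.0203). Os03g0850400 led the falls, from 134 ± 6.61 to 43.5 ± 7.09 CPM (-1.63 ± 0.32 on the log2 scale; edgeR adjusted p = 0.0176). In aoc leaf, Os09g0455300 rose from 2.26 ± 3.01 to 28.7 ± 11.7 CPM (3.67 ± 0.80; edgeR adjusted p = 0.0417). Os04g0602500 fell from 5.31 ± 0.632 to 1.60 ± 0.306 CPM (-1.73 ± 0.29; edgeR adjusted p = 0.0116). Each of the 4 calls was lost when single libraries were left out, while the log2 fold changes in those fits stayed at 6.90 to 7.59, -1.53 to -1.76, 3.20 to 3.95 and -1.72 to -1.85, in the order named. Os02g0824500 lost its call without WT 0 h replicate 1 (adjusted p = 0.0975), replicate 2 (0.113) or replicate 3 (0.104) or WT 1 h replicate 2 (0.0689). Os03g0850400 lost it without any 1 of the 6 libraries (0.0505 to 0.107). Os09g0455300 lost it without aoc 0 h replicate 1 (0.108) or replicate 2 (0.208) or any of the aoc 1 h replicates 1 (0.0820), 2 (0.0807) and 3 (0.143). It also lost it without the filter on low counts (0.0639) and with the compared groups alone (0.173). Os04g0602500 lost it without aoc 0 h replicate 2 (0.0777) or aoc 1 h replicates 1 (0.0531) and 3 (0.0564), and with the compared groups alone (0.0764).

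The leaf totals at 1 h, 311 in WT and 159 in aoc, moved with the libraries used. In WT, the total was 105, 55 and 46 without WT 0 h replicates 1, 2 and 3, and 53 and 104 without WT 1 h replicates 2 and 3. In aoc, it was 6 and 85 without aoc 0 h replicates 2 and 3, and 12, 78 and 19 without aoc 1 h replicates 1, 2 and 3. Of 671 identifiers that rose at least 8-fold in WT leaf at 72 h, 419 (62.4%) were at 1 CPM or more in leaf WT 1 h replicate 3 and 382 (56.9%) in leaf aoc 0 h replicate 3. The range was 169 to 274 (25.2% to 40.8%) in the other 10 leaf libraries of 0 and 1 h. The leaf 72 h libraries themselves were uneven. In WT replicates 1, 2 and 3 of 72 h the share was 60.4%, 85.4% and 89.3%. In aoc replicates 1, 2 and 3 of 72 h it was 57.4%, 47.5% and 82.3%. Without leaf WT 1 h replicate 3 and leaf aoc 0 h replicate 3, a choice made after seeing the data, 128 identifiers were called in WT and 85 in aoc. With the 6 leaf 72 h libraries left out of the fit, likewise chosen after seeing the data, 1221 were called in WT (723 higher, 498 lower) and 1065 in aoc (566 and 499). The compared groups alone gave 652 in WT and 0 in aoc by edgeR (3512 at an unadjusted p under 0.05). The replicate block gave 553 and 289, and DESeq2 934 and 670.

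**Figure D3:**
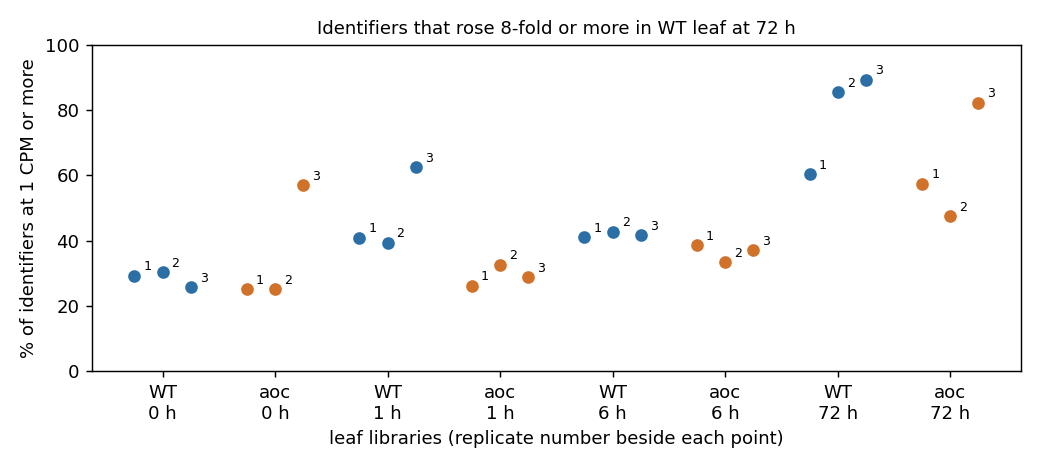
Percent of the 671 identifiers that rose at least 8-fold in WT leaf at 72 h that were at 1 CPM or more, with 1 point per leaf library (WT blue, aoc orange, replicate number beside it) by genotype and hours in NaCl. Leaf WT 1 h replicate 3 (62.4%) and leaf aoc 0 h replicate 3 (56.9%) stood above the other 10 libraries of 0 and 1 h (25.2% to 40.8%). The leaf 72 h libraries ranged from 47.5% (aoc replicate 2) to 89.3% (WT replicate 3).

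The leaf responses of WT and aoc were compared in the same way as in root, again with 1 estimate of the spread common to both genotypes. At 6 h, 3386 identifiers were higher and 2780 lower in both genotypes, 4.55 and 5.26 times the expected number, and at 72 h 2050 and 2319, 3.57 and 4.73 times. At 1 h, 40 were higher and 35 lower in both, 61.9 and 94.99 times the expected number (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 2.31e-63 and 2.19e-62). Across 14637 identifiers the log2 fold changes correlated at Pearson r = -0.0512 at 1 h, 0.895 at 6 h and 0.822 at 72 h (Spearman 0.524, 0.920 and 0.856). Without the identifiers that rose at least 8-fold at 72 h, which leaf WT 1 h replicate 3 and leaf aoc 0 h replicate 3 held at raised levels, r at 1 h was 0.549 over 14377. The 75 shared at 1 h became 34 without those 2 libraries, 435 with the leaf 72 h libraries left out of the fit and 0 with the compared groups alone, where edgeR called 0 in aoc (3512 at an unadjusted p under 0.05, 670 by DESeq2). Leaving out 1 library gave 48, 28 and 25 for WT 0 h replicates 1, 2 and 3, 46, 28 and 37 for WT 1 h replicates 1, 2 and 3, 42 and 4 for aoc 0 h replicates 1 and 2, and 6, 37 and 14 for aoc 1 h replicates 1, 2 and 3. The 4369 shared at 72 h became 557 with the compared groups alone, 2834 without WT 0 h replicate 3 and 2820 without WT 72 h replicate 3.

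The tissues were compared through the difference between the WT response in root and that in leaf. The response was more positive in root for 746 identifiers and more negative for 581 at 1 h, for 1859 and 2184 at 6 h, and for 2120 and 2413 at 72 h, of 27323 tested. Os05g0572000 led at 1 h, with 0.0496 ± 0.0352 CPM before and 13.4 ± 6.87 CPM after in root (SD, n = 3). In leaf it was at 2.98 ± 1.29 and 9.34 ± 2.66 CPM, a log2 difference of 6.32 ± 1.63 (edgeR adjusted p = 0.0171). It lost its call without root WT 0 h replicate 1 (log2 difference 6.05; adjusted p = 0.0541) or replicate 2 (6.08; 0.0593). At 6 h Os08g0474000 went from 2 reads to 36.9 ± 30.3 CPM in root and from 0.136 ± 0.120 CPM to 3 reads in leaf (edgeR adjusted p = 3.60e-05). Os06g0486900 went from 0.0926 ± 0.0549 to 5.67 ± 9.21 CPM in leaf and from 0.397 ± 0.488 to 0.1996 ± 0.0507 CPM in root (-6.85 ± 1.60 on the log2 scale; edgeR adjusted p = 0.00329). It lost its call without leaf WT 6 h replicate 1, where the log2 difference was -2.89 (adjusted p = 0.154), without root WT 0 h replicate 1 (-5.14; 0.0638) and with the compared groups alone (0.0663). The total of 1327 at 1 h became 842 without root WT 0 h replicate 2, 2731 with the leaf 72 h libraries left out and 2430 with the compared groups alone (1166 more positive and 1264 more negative). At 72 h the balance turned to 2376 more positive and 2161 more negative with RLE size factors. The total of 4533 at 72 h became 2504 without leaf WT 72 h replicate 3 and 1537 with the compared groups alone. Tissue went with the RNA extraction kit, so levels were not compared between tissues.

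Part of the WT response was nevertheless shared between the tissues. Of 23252 identifiers tested in both, 1096 were higher and 867 lower in root and leaf at 6 h, 2.17 and 2.33 times the expected number (Fisher's exact test, two-sided, adjusted p = 6.00e-175 and 1.36e-152). At 72 h, 680 and 535 were shared, 1.99 and 1.90 times the expected number (adjusted p = 3.68e-81 and 4.51e-55), and at 1 h, 139 and 42, 3.86 and 2.32 times (adjusted p = 1.36e-58 and 3.26e-08). At 6 h, 142 were higher in root and lower in leaf and 126 the reverse, and at 72 h 181 and 147. The 181 shared at 1 h became 95 without leaf WT 1 h replicate 3 and leaf aoc 0 h replicate 3 and 625 with the leaf 72 h libraries left out of the fit. It became 60, 38 and 32 without leaf WT 0 h replicates 1, 2 and 3 and 36 and 72 without leaf WT 1 h replicates 2 and 3. It rose to 384 with the compared groups alone, 328 with the replicate block and 483 with DESeq2. At 72 h the 1215 became 226 with the compared groups alone, 654 and 569 without root WT 0 h replicates 2 and 3, 628 without root WT 72 h replicate 2 and 721 without leaf WT 72 h replicate 3.

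The genotype comparisons asked what differed between aoc and WT at the same hour. At all 4 hours, 55 identifiers were higher and 46 lower in aoc root, and 33 higher and 36 lower in aoc leaf. Of these, 18 were higher and 10 lower in both tissues, against 0.0518 and 0.0503 expected. Os03g0115800 was at 412 ± 59.3 CPM in aoc root at 0 h and 0.0494 ± 0.0623 CPM in WT (SD, n = 3), a log2 difference of 12.93 ± 0.46 (edgeR adjusted p = 1.19e-12). In leaf at 0 h it was at 125 ± 28.2 CPM in aoc with no WT read, at least 4408-fold higher (edgeR adjusted p = 3.28e-08). Os07g0511400, first among those higher in aoc root at 6 h, was at 399 ± 46.2 CPM in aoc and 2 reads in WT, a ratio of 19751 with a counting interval of 5467 to 163098 (edgeR adjusted p = 2.56e-13). Os04g0397800 was at 9.62 ± 1.79 CPM in aoc leaf at 0 h with no WT read, at least 340-fold higher (edgeR adjusted p = 6.02e-07). At 72 h the leaf call of Os03g0115800 was lost with the compared groups alone in the fit (adjusted p = 0.0951), at a log2 difference of 10.96 rather than 11.00. In such fits 27 identifiers differed at all 4 hours in root and 0 in leaf, where edgeR called 0 at 72 h (1485 at an unadjusted p under 0.05, 1413 by DESeq2).

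Os11g0626700 led the identifiers lower in aoc root, with no read in any of the 12 aoc root libraries and 7.89 ± 2.14 CPM in WT at 0 h (SD, n = 3), at least 262-fold lower in aoc (edgeR adjusted p = 2.86e-05). In WT it was at 16.7 ± 1.93 CPM at 72 h, at least 537-fold above aoc (edgeR adjusted p = 9.24e-06). Os11g0625700 led in leaf, with no aoc read at 0, 1 and 6 h and 18.0 ± 2.37 CPM in WT at 0 h, at least 555-fold lower in aoc (edgeR adjusted p = 1.69e-05). It was at 42.3 ± 14.9 CPM in WT leaf at 6 h, at least 1321-fold above aoc (edgeR adjusted p = 6.57e-06). By the chromosome and order that the digits of the identifiers carry, both belong to a run of 5 on chromosome 11, from Os11g0623700 to Os11g0628000, without a read in any aoc root library. In WT root these 5 held 1191, 437, 1154, 5074 and 226 reads over 12 libraries. The run and its ends were chosen after their values were seen. In the 12 aoc leaf libraries Os11g0626700 held 33 reads, Os11g0628000 held 2 and the others none.

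**Figure D4:**
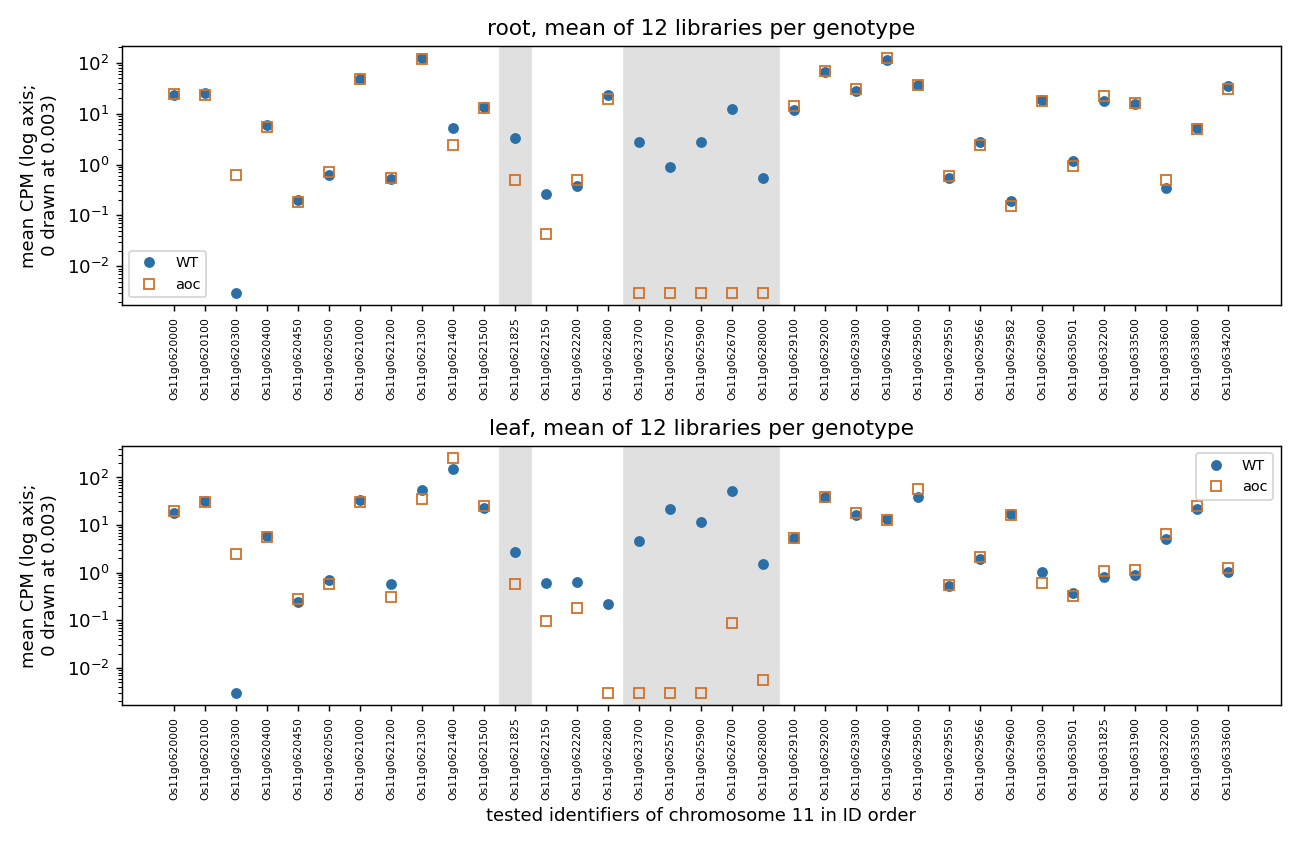
Mean CPM over 12 libraries per genotype (log axis, 0 drawn at 0.003) of tested identifiers of chromosome 11 in the order of their numbers, root above and leaf below, with WT as filled circles, aoc as open squares and grey bands over identifiers lower in aoc at all 4 hours. The 5 from Os11g0623700 to Os11g0628000 were at 0 in aoc root, while the tested neighbours on both sides, Os11g0622800 and Os11g0629100, held 7492 and 5389 aoc root reads. In leaf, Os11g0622800 held 0 aoc and 91 WT reads, so the first edge was seen in root only.

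Neighbouring identifiers were frequent among those that differed at all 4 hours. In root, 10 pairs were adjacent among the tested identifiers, against a mean of 0.276 and a maximum of 3 in 2000 permutations. In leaf there were 7 pairs, against 0.108 and 3. Most of the pairs in each tissue lay in the run of 5 on chromosome 11, the same in both, and a run of 3 on chromosome 1. They are thus not spread over the whole set. The permutation p was 5e-04 in each tissue, the smallest that 2000 permutations can give (adjusted p = 0.000571). Neighbours were also frequent among identifiers that changed at least 8-fold within WT root, with 40 pairs against 4.99 at 1 h, 44 against 4.63 at 6 h and 10 against 0.526 at 72 h. Of the identifiers different at all 4 hours, 5 of those higher and 5 of those lower in aoc root had no read in the 12 libraries of the lower genotype, and 3 and 3 in leaf. More than 100-fold differences numbered 18 higher and 6 lower in root and 12 and 8 in leaf, and differences under 4-fold 13 of 55 higher and 24 of 46 lower in root and 5 of 33 and 8 of 36 in leaf.

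At single hours, the genotype counts were 112 higher and 86 lower in aoc root at 0 h, 376 and 540 at 1 h, 271 and 424 at 6 h, and 484 and 364 at 72 h. In leaf they were 55 and 110 at 0 h, 616 and 489 at 1 h, 47 and 72 at 6 h, and 399 and 302 at 72 h. Over both tissues 3036 identifiers were called at 1 hour or more, 83 of them in opposite directions. With the compared groups alone, the root totals at 0, 6 and 72 h became 77, 292 and 104 and the leaf totals at 1 and 72 h 1679 and 0 (at 72 h 1485 at an unadjusted p under 0.05). With DESeq2 the totals at 0, 1, 6 and 72 h were 591, 1619, 1175 and 1898 in root and 553, 2115, 334 and 1413 in leaf. With the replicate number as a block they were 477, 1579, 1144 and 1709 in root, and 296 and 1670 in leaf at 0 and 1 h. The totals also moved with single libraries. In root at 0 h, 198 became 96, 108 and 130 without WT replicates 1, 2 and 3 and 303, 117 and 107 without aoc replicates 1, 2 and 3. At 1 h, 916 became 570 and 491 without WT replicates 2 and 3 and 496 and 585 without aoc replicates 2 and 3. At 6 h, 695 became 287 without WT replicate 3 and 419 without aoc replicate 3. At 72 h, 848 became 312 and 451 without WT replicates 2 and 3, and 2012, 257 and 269 without aoc replicates 1, 2 and 3. In leaf at 0 h, 165 became 86 and 93 without WT replicates 1 and 2 and 79 and 83 without aoc replicates 1 and 2. At 1 h, 1105 became 311, 418 and 546 without WT replicates 1, 2 and 3 and 367 and 271 without aoc replicates 2 and 3. At 6 h, 119 became 72 and 74 without WT replicates 1 and 2 and 58 and 75 without aoc replicates 2 and 3. At 72 h, 701 became 315 without WT replicate 3, and 456, 214 and 1937 without aoc replicates 1, 2 and 3. Which direction held more identifiers also turned. In root at 72 h it was 336 higher and 863 lower without WT replicate 1. In leaf at 1 h it was 118 and 193, 185 and 233, and 241 and 305 without WT replicates 1, 2 and 3, and 110 and 161 without aoc replicate 3. It was 804 and 875 with the compared groups alone. In leaf at 6 h it was 77 and 62 without aoc replicate 1, and in leaf at 72 h 143 and 172 without WT replicate 3 and 875 and 1062 without aoc replicate 3. Without leaf aoc 0 h replicate 3 and leaf WT 1 h replicate 3 the leaf total at 1 h was 557 (211 higher and 346 lower), and with the leaf 72 h libraries left out of the fit the totals were 396 at 0 h, 2633 at 1 h and 199 at 6 h.

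Some sets of identifiers that differed between genotypes at 1 hour overlapped with the WT salt response at another hour, a comparison without shared libraries once those called at all 4 hours were set aside. In root, 140 of 494 identifiers lower in aoc at 1 h (28.3%) had risen in WT at 6 h, against 13.0% of all tested (Fisher's exact test, two-sided, adjusted p = 8.01e-19). Those higher in aoc at 1 h showed no such excess at 6 h. Of these, 39 of 321 (12.1%) had risen (adjusted p = 0.886) and 47 (14.6%) had fallen (adjusted p = 0.223). At 72 h, 98 of the 494 (19.8%) had fallen in WT, against 9.73% of all tested (Fisher adjusted p = 4.44e-11), and 30 had risen. Of the 321, 62 (19.3%) had risen at 72 h, against 9.19% (Fisher adjusted p = 7.88e-08), and 17 had fallen. Of those lower in aoc at 6 h, 133 of 378 (35.2%) had risen in WT at 1 h, against 17.5% (adjusted p = 8.34e-16). At 72 h, 74 of the 378 (19.6%) had fallen in WT, against 9.73% (Fisher adjusted p = 2.72e-08), and 32 had risen. Of 429 higher in aoc root at 72 h, 147 (34.3%) had risen in WT at 6 h (adjusted p = 6.26e-29). The root overlaps were not rerun with libraries left out, and the root total of 848 at 72 h became 257 without aoc 72 h replicate 2. Fisher's test counts identifiers as independent, though they can vary together, so 1 deviating library could make such an overlap. Both calls also share the spread estimate of 1 fit, which tends to raise overlaps. In leaf, 275 of 583 higher in aoc at 1 h (47.2%) had fallen in WT at 72 h, against 13.6% (adjusted p = 6.34e-86). Without leaf WT 1 h replicate 3 and leaf aoc 0 h replicate 3, 72 of 181 (39.8%) had fallen, and with the leaf 72 h libraries left out of the genotype fit 504 of 1300 (38.8%). For leaf identifiers that differed at 6 h, only 14 higher and 36 lower in aoc, no overlap was called (lowest Fisher adjusted p = 0.0530). That value belonged to 10 of the 36 (27.8%) that had fallen in WT at 72 h. Of 366 higher in aoc leaf at 72 h, 94 (25.7%) had risen in WT at 6 h, against 15.6% (Fisher adjusted p = 2.45e-06), and 29 had fallen. The leaf genotype total of 701 at 72 h became 214 without aoc 72 h replicate 2.

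The last comparison tested whether the change from 0 h itself differed between aoc and WT. In root at 1 h, 3 identifiers passed, all with a more negative change in aoc. Os01g0834900 rose in WT from 15.9 ± 3.69 to 38.0 ± 9.43 CPM (SD, n = 3) and fell in aoc from 9.45 ± 2.12 to 3.00 ± 0.720 CPM. The log2 difference was -2.90 ± 0.36 (edgeR adjusted p = 0.00194). Os11g0482901 rose in WT from 13.5 ± 2.92 to 35.4 ± 5.38 CPM and fell in aoc from 7.04 ± 1.67 to 3.22 ± 0.795 CPM. The log2 difference was -2.52 ± 0.29 (edgeR adjusted p = 0.00118). Within each genotype both changes passed, with edgeR adjusted p = 0.000562 in WT and 7.81e-05 in aoc for Os01g0834900. For Os11g0482901 these were 2.38e-05 and 0.000356. In leaf at 6 h, Os09g0541000 rose in aoc from 4.77 ± 0.584 to 158 ± 17.9 CPM and in WT from 16.4 ± 1.95 to 132 ± 12.1 CPM, a log2 difference of 2.04 ± 0.29 (edgeR adjusted p = 0.0251). With the compared groups alone in the fit, the adjusted p was 0.0656 for Os01g0834900 and 0.0727 for Os11g0482901, at log2 differences of -2.89 and -2.50. Os09g0541000 lost its call with the leaf 72 h libraries left out (adjusted p = 0.188) and without any 1 library except aoc 6 h replicate 1 and WT 0 h replicate 1 (0.0683 to 0.175). Its log2 difference stayed at 2.04 in the first of these fits and at 1.94 to 2.11 in the others.

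In root at 6 and 72 h and in leaf at 1 and 72 h, edgeR called 0 identifiers in this test. In root, unadjusted p was under 0.05 for 1140 identifiers at 1 h, 1083 at 6 h and 1412 at 72 h, where 1310 would be due to chance, and DESeq2 called 27, 16 and 32. In leaf the numbers were 1183, 457 and 1466, where 1216 would be due to chance, and DESeq2 called 57, 9 and 23. Leaving out 1 library gave calls in some of these. In root at 72 h there were 17 without aoc 72 h replicate 1 and 1 without WT 72 h replicate 2 or 3 or aoc 0 h replicate 3. In root at 6 h there were 21 without WT 6 h replicate 2 and 1 without aoc 0 h replicate 2 or 3. In leaf at 72 h there were 16 without WT 72 h replicate 1 and 1 without aoc 72 h replicate 1. In counts simulated from these libraries, the same test recovered 0% of 1.5-fold, 34% of 2-fold, 66% of 4-fold and 96% of 8-fold differences between root responses. Between leaf responses it recovered 0%, 6%, 44% and 66%.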

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

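Written or chosen only after the result was seen were the splits of the root libraries, the tests for a wrong label between genotypes and for mixed reads, the number of splits drawn between tissues, and the alternatives with 2 leaf libraries or the leaf 72 h libraries left out.

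The change from 0 h in WT differed between root and leaf for 1327 identifiers at 1 h, 4043 at 6 h and 4533 at 72 h. Of 46 splits of the 12 libraries, 6, 5 and 3 gave as many, with 2977, 5500 and 5070 in the highest other split. These splits exchange hours within a tissue, and those with 2977 and 5070 exchanged 2 of 3 libraries in 1 tissue and none in the other. Such splits can carry or add the changes of root and leaf themselves, so they do not show whether chance is excluded. At an unadjusted p under 0.05 there were 5106, 7550 and 8420 identifiers, against 1366 expected without any difference.

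In root at 1 h, the change from 0 h differed between the genotypes for 3 identifiers. Of 31 splits of the 12 libraries, 4 gave as many, with 162 in the highest other split. In leaf at 6 h it differed for 1 identifier, and 2 of 31 splits gave as many, with 506 in the highest other split. At 6 and 72 h in root, 31 of 31 splits reached the real count of 0 (highest other 1 and 12), and likewise in leaf at 1 and 72 h (highest other 0 and 1692). Any split reaches a count of 0, so these shares carry no information. These splits exchange genotypes within an hour, and those with 162 and 506 exchanged 2 of 3 libraries at 1 of the 2 hours and none at the other. Such splits can carry the difference between the genotypes itself, so they do not show whether chance is excluded. For the 4 counts of 0 edgeR had 1083 and 1412 identifiers in root and 1183 and 1466 in leaf at an unadjusted p under 0.05, and DESeq2 called 16, 32, 57 and 23.

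The 1st pattern weighed is the set of identifiers that differed between the genotypes at all 4 hours, 101 in root and 69 in leaf. Swapped or wrong labels are argued against: scored on identifiers picked in the other tissue, 0 of 48 libraries sided with the other genotype. Stretches of sequence that differ between the lines stay open. Among identifiers different at all 4 hours, neighbouring pairs exceeded permuted ones 14.0 times more in root than among those different at 1 hour alone. In leaf this was 52.3 times. The sets held 101 and 69 identifiers against 1217 and 1167, with 10 and 7 pairs against 80 and 38. Most of the 10 and 7 pairs lay in the runs on chromosomes 11 and 1. Permuted pairs grow faster than the set, so a smaller set tends to a higher ratio and this comparison cannot decide. Neighbours were also frequent among changes of 8-fold or more within WT (10 pairs against 0.526 in root at 72 h). A loss of induction by jasmonate stays open. Of 49 identifiers lower in aoc root at 0, 6 and 72 h, 14 (28.6%) had risen in WT root at 1 h. Of all tested it was 17.5%, an odds ratio of 1.89 (95% interval 0.937 to 3.599, Fisher's exact test p = 0.0571). The root WT 0 h libraries entered both sides, which tends to lower this ratio. All 49 were called lower at 0 h, before salt, so induction by salt alone cannot account for that difference. The mutation itself and the background of the line were not tested.

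The 2nd pattern is the raised level, in leaf aoc 0 h replicate 3 and leaf WT 1 h replicate 3, of identifiers that rose at 72 h. A 72 h library under a wrong label is argued against, because the identifiers that fell at 72 h showed only 7.42% and 10.8% of their fall in these libraries, while those that rose showed 69.4% and 46.6% of their rise. Reads mixed in from a 72 h library of the same genotype could not be decided: the 90th over the 10th percentile of the ratio to such a library was at least 7.09 and 9.81, between the bounds of 4 and 10, after a minimum of 20 identifiers per library was set because the first version rested on 2 or 4. Reads from the other genotype are argued against for leaf WT 1 h replicate 3 only with aoc 72 h replicate 3 as their source. There, 1.45% of the expected reads were found. For leaf aoc 0 h replicate 3 they could not be decided. It held 21 reads over 9 identifiers, 54.5% of the 39 expected from WT 72 h replicate 2 and 16.8% of the 125 from replicate 3. The 90th over the 10th percentile of the ratio to these sources was 18.3 and 10.3. Both lie above the bound of 10 set for the same genotype, which speaks against 1 share of mixed reads. The other sources (at most 8.15% and 2.84%, in the order of the libraries) missed the minimum and stay open. An early start of the 72 h response in some plants, each library holding 3, was not tested.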

How the results depend on the processing

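In this part, alternatives with root WT 1 h replicate 3 thinned, with 2 leaf libraries left out and with the leaf 72 h libraries left out of the fit, and the same alternatives for the derived counts, were chosen after the data were seen. No named identifier reversed its direction under any alternative run. Which of the higher and lower calls were more numerous did turn in several counts. For aoc against WT in leaf at 1 h, 616 and 489 became 804 and 875 with the compared groups alone and 211 and 346 with 2 leaf libraries left out. For aoc root at 6 h, 4381 and 4353 became 4211 and 4514 with RLE factors, and for the tissue difference at 72 h, 2120 and 2413 became 2376 and 2161. RLE size factors left 41 of 41 counts within 1.5 times, and thinning 8 of 8; no filter on low counts moved 1 of 41, the identifiers shared by WT and aoc in leaf at 1 h (46). Of the named identifiers, 0 of 93 lost their call with DESeq2, 0 of 95 with RLE factors or the replicate block, 0 of 14 with thinning and 2 of 95 without the filter. It was 24 of 91 with the compared groups alone, 3 of 29 with 2 leaf libraries left out and 1 of 37 with the leaf 72 h libraries left out. When 1 library was left out, the call was lost in 87 of 660 values, where an identifier counts once per fit. The share of named identifiers that lost their call in at least 1 of these fits was larger. Without scaling factors the median log2 difference of all genes between aoc and WT leaf at 1 h moved by -0.29 from its TMM value; all changes are given relative to TMM. Depth limits what is seen near the floor of 3 counts, and the simulated data show that 1.5-fold changes were mostly missed. The gene list tests and the tissue markers, with their alternatives, were not run because no list member could be matched.

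DESeq2 moved 22 of 41 counts, all upward; the cause was not tested for these or the other moved values. It called 57, 9 and 23 identifiers for the genotype difference of the changes in leaf at 1, 6 and 72 h and 27, 16 and 32 in root. For aoc against WT at 0, 1, 6 and 72 h it called 553, 2115, 334 and 1413 in leaf and 591, 1619, 1175 and 1898 in root. At all 4 hours it called 143 in leaf, 190 in root and 45 in both. It called 934 for the change at 1 h in WT leaf, 670 in aoc leaf and 267 in both, 483 shared by root and leaf at 1 h, and 2184 for the tissue difference at 1 h.

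With the compared groups alone in the fit, so with fewer libraries to estimate the spread, 4 counts moved up and 18 down. The genotype difference of the changes in root at 1 h fell to 1. For aoc against WT, leaf had 1679 at 1 h and 0 at 72 h by edgeR (1485 at an unadjusted p under 0.05, 1413 by DESeq2). In root it was 77 at 0 h, 292 at 6 h and 104 at 72 h. At all 4 hours it was 27 in root, 0 in leaf and 0 in both. Changes from 0 h numbered 652 and 1766 in WT leaf at 1 and 72 h, 0 by edgeR (3512 at an unadjusted p under 0.05, 670 by DESeq2) and 1508 in aoc leaf, 2522 in WT root at 72 h and 2100 in aoc root at 72 h. WT and aoc shared 0 at 1 h and 557 at 72 h in leaf and 1074 at 72 h in root. Root and leaf shared 384 at 1 h and 226 at 72 h, and the tissue difference had 2430 at 1 h and 1537 at 72 h.

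The replicate numbers were not taken to pair the libraries, because the labels name no shared batch. On average, libraries with the same number did deviate together, which the main fits leave out. Deviations from the group mean correlated within a tissue at a mean r of 0.177 in root and 0.170 in leaf between libraries with the same number, across genes. Of 84 such pairs, 58 in root and 52 in leaf were over 0.1, and the lowest were at -0.149 and -0.136. By number, the mean r for 1, 2 and 3 was 0.224, 0.0624 and 0.245 in root and 0.198, 0.0299 and 0.283 in leaf. Between libraries with different numbers the mean r was -0.0884 in root and -0.0843 in leaf. Deviations cancel out within a group, so negative values between different numbers largely follow from the positive ones, here and across tissues. Of 24 libraries, 21 in root and 17 in leaf correlated best with their own number. Across tissues, between root and leaf libraries of 1 genotype and hour, the mean r was 0.113 over 24 pairs of the same number. Over 48 pairs with different numbers it was -0.0564, a difference of 0.170 (permutation test, one-sided, p = 9e-05). Between different groups it was 0.0447 for the same number and -0.0220 for different numbers. A batch shared by root and leaf may exist, but the test does not tell it from another link within a group. As a replicate block, the number moved 11 of 41 counts, all upward. For aoc against WT these became 296 and 1670 in leaf at 0 and 1 h, 477, 1579, 1144 and 1709 in root at 0, 1, 6 and 72 h, and 168 at all 4 hours in root. The change at 1 h had 553 in WT leaf, 289 in aoc leaf, 136 in both, and 328 shared by WT root and leaf.

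With the 2 leaf libraries left out, 5 of 16 counts moved down. At 1 h these were 557 for aoc against WT in leaf, 128 for the change in WT leaf, 85 in aoc leaf, 34 in both and 95 shared by root and leaf. With the leaf 72 h libraries out of the fit, which removes the most variable groups from the estimate of the spread, 9 of 17 moved. They were 396, 2633 and 199 for aoc against WT in leaf at 0, 1 and 6 h, 0 for the genotype difference of the changes at 6 h by edgeR (878 at an unadjusted p under 0.05, 9 by DESeq2). At 1 h they were 1221 in WT leaf, 1065 in aoc leaf, 435 in both, 625 shared by root and leaf, and 2731 for the tissue difference.

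Leaving out 1 library left 330 of 432 counts within 1.5 times and moved 12 up and 90 down. The ranges for the change at 1, 6 and 72 h were 7219 to 7644, 4306 to 5603 and 2215 to 4427 in WT root, 7045 to 8770, 6067 to 8167 and 2373 to 5138 in aoc root. In leaf they were 46 to 217, 4976 to 6038 and 3561 to 8608 in WT, and 6 to 106, 6584 to 8004 and 4382 to 7698 in aoc. For aoc against WT at 0, 1, 6 and 72 h they were 96 to 303, 491 to 731, 287 to 644 and 257 to 2012 in root and 79 to 154, 271 to 861, 58 to 139 and 214 to 1937 in leaf. At all 4 hours they were 72 to 101 in root, 48 to 69 in leaf and 24 to 28 in both. The genotype difference of the changes ranged over 3 to 4, 0 to 21 and 0 to 17 in root at 1, 6 and 72 h, and 0 to 1 at 6 h and 0 to 16 at 72 h in leaf. The tissue difference ranged over 842 to 1170, 3089 to 3898 and 2504 to 6535. WT and aoc shared 5721 to 6528, 3649 to 4830 and 1554 to 2543 in root and 4 to 52, 4581 to 5766 and 2820 to 4879 in leaf. Root and leaf shared 32 to 170, 1333 to 1772 and 569 to 1392.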

Other observations

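In this part the splits of the root libraries, the permutation test of the 50 most abundant identifiers, and the reading of it beside the leaf 72 h groups, were chosen after the result was seen; the splits of the leaf libraries were planned.

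In leaf, the 50 most abundant identifiers of each library took a larger share of the counts in aoc than in WT. The mean over the 4 hours was 24.3% in aoc and 19.3% in WT, a difference of 5.01 percentage points (exact permutation test within hours, two-sided, p = 1e-04 over 160000 relabellings). By group the share was 24.9% ± 0.706 (SD, n = 3) in aoc and 21.2% ± 2.12 in WT at 0 h, 27.8% ± 1.98 and 19.6% ± 1.25 at 1 h, 25.2% ± 3.51 and 20.8% ± 2.32 at 6 h, and 19.2% ± 1.37 and 15.5% ± 1.31 at 72 h.

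Runs of neighbouring identifiers were also found among those that changed at least 8-fold in WT. In root at 6 h, 5 neighbours from Os01g0871733 to Os01g0872100 were higher, and 4 from Os10g0551700 to Os10g0552300 lower. In leaf at 6 h, 4 from Os01g0945200 to Os01g0945400 were higher. These runs were chosen after their values were seen.

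Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05, and the real one and the highest other called as follows. Every other split mixes the compared groups on both sides, so a real difference becomes spread within them and lowers their calls. A low count in the other splits is therefore no separate evidence. For the change from 0 h at 1, 6 and 72 h, WT root had 8924, 6523 and 4955 against 0, 0 and 0, and aoc root 9085, 8734 and 5189 against 1, 0 and 132. WT leaf had 311, 7108 and 6964 against 0, 0 and 0, and aoc leaf 159, 8652 and 7422 against 0, 0 and 152. For aoc against WT at 0, 1, 6 and 72 h, root had 198, 916, 695 and 848 against 0, 139, 67 and 358. Leaf had 165, 1105 and 119 at 0, 1 and 6 h against 0, 0 and 0. At 72 h in leaf, 4 of the 10 splits reached the real 701. The highest other, which set aoc replicates 1 and 2 and WT replicate 2 against the rest, called 4075, which points to a structure of these 6 libraries other than genotype.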
